A study of Homo sapiens with 16 samples.

How the data were processed

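RNA was sequenced from the human melanoma line UACC62P and its vemurafenib-resistant derivative UACC62R, untreated or after 2, 6 or 24 h in 10 uM CCG-222740, with 2 libraries in each of 8 groups. Per the labels' protocols, stranded poly(A) libraries were read as single 50 bp reads on a HiSeq 4000. Per the submitters' processing notes, the tools were bcl2fastq 2.19.0, FastQC 0.11.5, Trimmomatic 0.33, HISAT2 2.1.0 and HTSeq 0.6.1, with the genome build hg19. The strand setting of the counting is not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. The authors deposited 1 table per library of raw read counts for 63677 Ensembl gene IDs, followed by 5 summary lines on reads not assigned to a gene, with no normalization. These lines stayed out of library sizes and tests. Over the 16 libraries, 6.12 to 17.8% of all reads were not aligned and 18.6 to 22.0% aligned to more than 1 place. Of the uniquely aligned reads, 3.31 to 4.66% lay in no gene and 5.99 to 6.81% in more than 1. Reads in genes numbered 25.9 to 33.3 M per library. Reads aligned to more than 1 place were not counted for a gene, so genes with near-identical copies are undercounted.

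Gene symbols came from a table of Ensembl IDs and names, which held 52181 of the IDs, and gene types from GENCODE annotation of another build, from which no coordinate was taken. The groups and replicate numbers came from the sample labels. Library sizes were scaled by TMM, genes were kept by filterByExpr on the groups (19352 genes in 16 libraries), and each of 12 comparisons was tested by edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in 1 fit with a coefficient per group (8 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were 2, 6 and 24 h against 0 h in each line, UACC62R against UACC62P at 0 h, the difference of response between the lines at each time, and 24 h against 2 h in each line. A standard error is the log2 fold change divided by the square root of its F statistic. CPM values were scaled by TMM, within the 15 libraries for group means and within 16 for the library labelled UACC62P 2 h replicate 1 and the values set beside MT1X there.

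The tests, the gene lists, the rule for named genes and the other fits listed at the end, except those without the library labelled UACC62P 2 h replicate 1, were fixed before the data were examined. For 24 h against 0 h and for the lines at 0 h, the rule took the 10 called genes with the largest log2 fold change each way among those with a mean log2 CPM of at least 2 and no overlap between the groups, and 5 each way for the other comparisons, with no condition on overlap for differences of response. It passed over unnamed clones, pseudogenes, LOC symbols and antisense RNAs. It was applied to the 16-library fit and, after seeing the data, to the 15-library fit. From each list it took up to 4 called members with a mean log2 CPM of at least 0, or the one with the smallest p. MRTFA, MRTFB, SRF, MITF, SOX10, AXL, NGFR, BRAF, ACTA2, TAGLN, CCN2, CCN1 and ANKRD1 were among those always to be given.

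The 21 lists held 406 entries, 405 with an ID, and included MRTF/SRF cytoskeletal targets, immediate early genes, YAP/TAZ targets, melanocyte differentiation, dedifferentiated/invasive melanoma, MAPK pathway output, G1/S and DNA replication, G2/M and mitosis, p53 targets, cholesterol synthesis, ATF4/amino acid response, ER chaperones, NRF2 targets, aryl hydrocarbon receptor targets, interferon-stimulated genes, NF-kB targets and cytokines, heat shock response, extracellular matrix, glycolysis and hypoxia, and markers of other cell types (epithelial, endothelial, blood). Each was tested by camera (limma) on log2 CPM (prior count 2) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists within a comparison. Members called were counted over all genes and adjusted over the list alone. Over the 12 comparisons in 16 libraries, camera called 63 list tests with the preset and 0 with an estimated correlation. In 15 libraries it called 70 and 1, the latter melanocyte differentiation between the lines at 0 h.

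The library labelled UACC62P 2 h replicate 1 resembled UACC62R, so every comparison was also fitted in 15 libraries without it (20280 genes, 7 residual degrees of freedom), a choice made after seeing the data. The replicate numbers are shared by all groups in the labels. Deviations from the group means correlated between same-numbered libraries in all 21 pairs of groups without UACC62P 2 h (0.17 to 0.72 over 8281 genes with a mean log2 CPM over 4; 0.32 to 0.54 within UACC62P, 0.65 to 0.72 within UACC62R, 0.17 to 0.50 between the lines). The numbers were therefore taken to pair the libraries, from the data and not from a label, and fits with the replicate number as a block are given beside the counts. In the 7 pairs with UACC62P 2 h the correlations were -0.04 to 0.15.

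Other fits and settings were RLE scaling, scaling by library size alone, a filter of 1 count in any library or of 5 CPM in 2 libraries, a minimum absolute log2 fold change of 1, only the libraries compared, DESeq2 1.42.0, the replicate block, each library left out in turn, an estimated correlation and fry for lists, and a set of line genes at 0 h or with a minimum absolute log2 fold change of 2 (1 in the main set). The position of a library between the lines was computed from log2 CPM relative to the 6 h libraries. The fits were tested on counts simulated from the real group means, library sizes and dispersions. There UACC62R at 24 h was set to its 0 h means plus known changes. The library labelled UACC62P 2 h replicate 1 was set to UACC62R 0 h means. The p-values of the sets of line genes were adjusted over both sets in both lines, and those of the ER translocation and N-glycosylation genes over the 12 comparisons, by Benjamini-Hochberg and after seeing the data. Correlations and overlaps between the lines were computed across genes, with no p. Sequence positions were not used here. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.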

Results

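Messenger RNA was sequenced from a pair of related human melanoma lines. UACC62P is the parental line, and UACC62R was derived from it by growth in 2 uM vemurafenib, an inhibitor of mutant BRAF, for 2 months and was kept in the drug afterwards. Each line was exposed to 10 uM CCG-222740, a compound known as an inhibitor of gene activation through the SRF coactivators MRTFA and MRTFB, for 2, 6 or 24 h, or was left untreated (0 h). This gave 8 groups of 2 libraries. The 16 libraries held 25.9 to 33.3 M reads assigned to genes (median 29.9 M). In M reads, replicates 1 and 2 of UACC62P held 30.2 and 28.2 at 0 h, 30.7 and 25.9 at 2 h, 33.3 and 27.3 at 6 h, and 30.5 and 28.6 at 24 h. Those of UACC62R held 29.6 and 31.0 at 0 h, 28.6 and 27.0 at 2 h, 31.0 and 28.9 at 6 h, and 30.2 and 32.6 at 24 h. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No vehicle library was used here, so each comparison with 0 h holds the compound, its vehicle and the time in culture together. The 0 h libraries also carry other label texts than the treated ones, so a separate batch for them remains possible. Vemurafenib in the medium is stated for the 0 h libraries of UACC62R, and for the treated ones it is not given in the sources used here, so a change of vemurafenib is not separated from the compound in that line.

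The library labelled UACC62P 2 h replicate 1 did not match its line. On a scale set by 244 genes, where the 6 h libraries of UACC62P lie at 0 and those of UACC62R at 1, it lay at 0.984, within the range of the UACC62R libraries (0.962 to 1.008). The other 7 UACC62P libraries lay between -0.031 and 0.003. SOX10 (ENSG00000100146), a transcription factor of the melanocyte lineage, stood at 18.1 CPM in it, against group means of 773 to 853 CPM in the other UACC62P libraries and 21.8 to 28.4 CPM in UACC62R. The receptor kinase AXL stood at 196 CPM, against 2.64 to 4.73 CPM and 175 to 270 CPM. The collagen gene COL1A1 stood at 267 CPM, against 3.31 to 4.88 CPM and 277 to 416 CPM. The 2 libraries of the UACC62P 2 h group differed by a chi-square of 301 per degree of freedom, against 9.37 to 19.2 for the other 7 pairs. Over the 15 genes that passed the test at 2 h in UACC62R (15 libraries), this library lay nearer to untreated UACC62R than to UACC62R at 2 h for 14. MT1X, for example, stood at 59.1 CPM, against 52.0 CPM in UACC62R at 0 h and 297 CPM at 2 h.

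**Figure D1:**
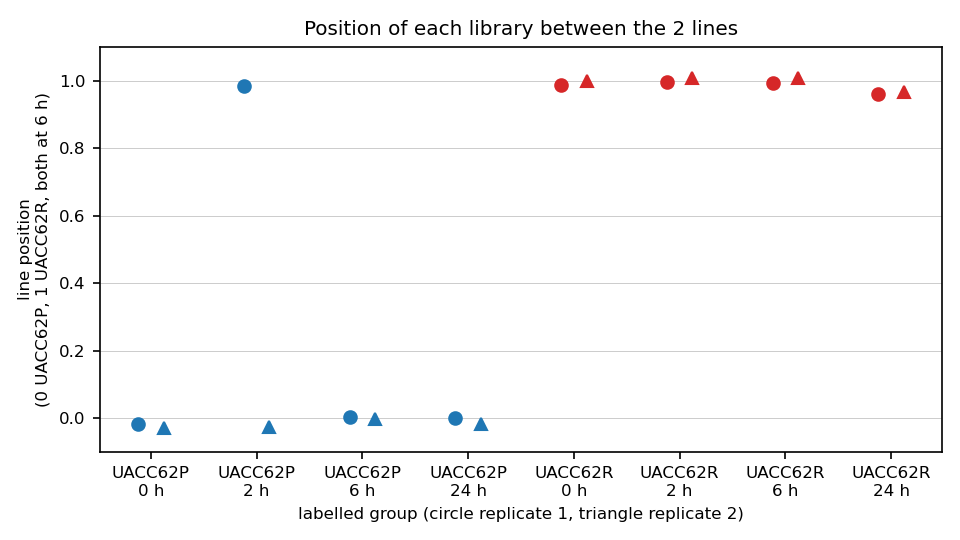
Line position of each of the 16 libraries (vertical axis, no unit, from 244 genes; 0 is the mean of the UACC62P and 1 that of the UACC62R libraries at 6 h) by labelled group (horizontal axis), with a circle for replicate 1 and a triangle for replicate 2. The library labelled UACC62P 2 h replicate 1 lies at 0.984, among the UACC62R libraries, and the other 15 lie with their lines.

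This library raised the spread in the fit of all 16 libraries, whose common dispersion was 0.0622, against 0.00985 in the fit of the 15 others. The library differed from the other of its group as the lines differ. The 16-library fit can therefore most easily miss changes in genes that differ between the lines. Each count of genes is therefore given first for the 16 libraries, then for 15 libraries without the library labelled UACC62P 2 h replicate 1, a choice made after seeing the data. Another count comes from the 15 libraries with the replicate number as a block. The 15-library fit gave the fold changes, the genes called and the list counts, unless the 16 libraries are named. Log2 fold changes are printed with their standard errors for n = 2 against 2, except that UACC62P at 2 h had n = 1 and was assumed to vary like the other groups. In simulated data for UACC62R at 24 h against 0 h (19820 genes), the 15-library fit recovered 46 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 10 false calls. The 16-library fit recovered 9, 39 and 59 of them among 19299 genes, with 0 false calls. The changed genes were drawn only from those above a minimum level in UACC62R at 0 h. The library labelled UACC62P 2 h replicate 1 was given UACC62R 0 h levels, so a loss in 16 libraries was built in. Deviations shared by same-numbered libraries were not simulated. MT1 genes, HSPA1A and HSPA1B, the AKR1C genes, and FTH1 have near-identical copies or pseudogenes, and their values are uncertain because reads aligned to more than 1 place were not counted.

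Before treatment with CCG-222740, the comparison of the lines asked how the vemurafenib-resistant cells differed from their parent. Vemurafenib is stated for the UACC62R libraries at 0 h and not for those of UACC62P. Resistance and the presence of vemurafenib are therefore not separated in this comparison. UACC62R expressed genes of the melanocyte lineage far below UACC62P and genes of the extracellular matrix, of invasive melanoma and of the actin cytoskeleton above it. SOX10 was lower by -5.03 ± 0.12 (26.1 ± 0.203 against 853 ± 93.8 CPM, SD, n = 2 each), and the melanocyte regulator MITF by -2.21 ± 0.11. TYR, the rate-limiting enzyme of melanin synthesis, was lower by -9.51 ± 0.18, and the growth factor receptor ERBB3 by -8.39 ± 0.12. AXL was higher by 6.23 ± 0.17 (248 ± 27.2 against 3.30 ± 0.182 CPM, SD). In 16 libraries, edgeR's quasi-likelihood test called 4167 genes higher and 3680 lower in UACC62R. It called 5642 and 5297 in 15 libraries, and 6090 and 5806 with the replicate block.

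The largest differences upwards, all called in both fits, were in ADAMTS2 (9.53 ± 0.30), which trims procollagen, EFEMP1 (9.12 ± 0.21), a matrix glycoprotein, the potassium channel gene KCNJ15 (9.09 ± 0.14), the chemokine gene CCL2 (9.03 ± 0.35), TENM2 (8.85 ± 0.14), BEX1 (8.82 ± 0.23), the protease gene ADAMTS12 (8.64 ± 0.17), TNFRSF11B (8.53 ± 0.22), which encodes osteoprotegerin, the matrix gene POSTN (8.48 ± 0.31) and SCARA3 (8.42 ± 0.25). The largest downwards included the lipoprotein lipase gene LPL (-8.06 ± 0.17), the fatty acid-binding gene FABP7 (-8.36 ± 0.17), ITIH5 (-8.92 ± 0.18), the BMP antagonist CHRDL1 (-9.36 ± 0.22), ITIH6 (-9.47 ± 0.34) and the connexin gene GJB1 (-9.93 ± 0.15). PMP2, a myelin protein gene, and RXRG, a retinoid receptor gene, had only 7 and 4 reads over both UACC62R libraries, so levels are given in place of a fold: 143 ± 5.77 CPM and 125 ± 14.0 CPM in UACC62P (SD, n = 2). Among the genes of the targeted pathway, CCN1 (3.22 ± 0.14), TAGLN (3.02 ± 0.38), CCN2 (2.42 ± 0.13), ACTA2 (1.19 ± 0.11), MRTFA (0.97 ± 0.09) and MRTFB (0.81 ± 0.16) were higher in UACC62R. SRF (0.21 ± 0.09), BRAF (-0.17 ± 0.11) and NGFR (-0.99 ± 0.41) did not pass the test in either fit. ANKRD1 had 52 reads in UACC62R and 2 in UACC62P, a ratio of 23.7 (95% counting interval 6.24 to 201).

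Of 17 melanocyte differentiation genes tested, 13 were lower and 1 higher in UACC62R, MLANA (-8.05) and SLC24A5 (-6.49) among the lower ones (2 higher and 13 lower when adjusted over the list alone; median -2.40, camera adjusted p = 5.26e-06). That call held with an estimated correlation in 15 libraries (adjusted p = 0.0328) and was lost with it under the replicate block (adjusted p = 0.0815) and in 16 libraries (adjusted p = 0.461). Of 20 genes of dedifferentiated or invasive melanoma, 14 were higher and 3 lower, with SOX9 (6.12), THBS1 (5.97) and ITGA3 (5.34) among the higher ones (14 and 4 adjusted over the list alone; median 3.61, camera adjusted p = 3.79e-05). Of 23 MRTF/SRF cytoskeletal targets, 19 were higher and 1 lower, with FHL1 (4.30), CNN2 (2.71) and TPM1 (2.51) among the higher ones (21 and 1 adjusted over the list alone; median 1.18, camera adjusted p = 1.20e-06). The YAP/TAZ targets were higher in 16 of 22 genes and lower in 1, TGFB2 (-3.68), with the same counts adjusted over the list alone (median 1.72, camera adjusted p = 0.000184). All 3 list calls were lost with an estimated correlation (adjusted p = 0.369, 0.176 and 0.369).

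Of 24 extracellular matrix genes, 15 were higher and 6 lower, led by POSTN, COL5A1 (7.49), COL6A3 (7.42) and COL1A1 (6.70) (16 and 6 adjusted over the list alone; median 1.49, camera adjusted p = 0.00197). The cholesterol synthesis genes were lower in 18 of 23, including MVK (-2.02) and DHCR7 (-1.37), and higher in 0, with the same counts adjusted over the list alone (median -0.82, camera adjusted p = 3.79e-05). Interferon-stimulated genes were higher in 12 of 19 and lower in 1, with IFI44L (3.16) and OAS2 (2.90) among them (camera adjusted p = 0.0136). NF-kB targets and cytokines were higher in 10 of 17 and lower in 3, with CXCL1 (5.79), CXCL8 (4.55) and IL1B (3.27) (camera adjusted p = 0.0228). NRF2 targets were higher in 11 of 18 and lower in 2, with AKR1B10 (4.27) (camera adjusted p = 0.0266). Adjusted over the list alone, the first of these lists had 12 and 1, the second 10 and 3, the third 12 and 2. These 5 calls were also lost with an estimated correlation (adjusted p = 0.552, 0.369, 0.176, 0.369 and 0.552, in that order).

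Another 11 lists were not called at 0 h. Members went both ways among immediate early genes (6 higher and 9 lower of 18; NR4A1 -3.71, FOS -2.82, JUN 1.97), MAPK pathway output (5 and 6 of 15; EPHA2 4.87, SPRY4 -2.31), p53 targets (6 and 8 of 20; CDKN1A 1.16, GDF15 -0.92) and glycolysis and hypoxia (10 and 5 of 19; CA9 4.02, EGLN3 3.10). For MAPK output the median (-0.21) and the test pointed down and the mean (0.13) up, and for p53 targets the median (-0.12) and the test pointed down and the mean (0.08) up. The remaining counts were 2 higher and 10 lower of 24 for G1/S and DNA replication (MCM6 -1.06), 5 and 0 of 24 for G2/M and mitosis (CDC25C 1.05), 2 and 8 of 19 for the ATF4 and amino acid response (TRIB3 -1.51), 2 and 9 of 15 for ER chaperones (SEL1L -0.83), 3 and 0 of 4 for aryl hydrocarbon receptor targets (TIPARP 0.89) and 5 and 2 of 12 for the heat shock response (HSPA1A 1.67). Of 11 tested markers of epithelial, endothelial and blood cells, 4 were higher and 3 lower (KRT8 1.77, KRT18 1.56, ESRP1 -6.38), with a median of 1.11 and a test pointing up but a mean of -0.92. In the 16 libraries the call count for the lines fell to 0 without either UACC62P 0 h library, to 2 without UACC62R 0 h replicate 1 and to 2834 without replicate 2, whereas in 15 libraries it stayed between 9304 and 9630. Scaling by library size alone moved the median log2 fold change of all genes to 0.102, from 0.0216 with TMM.

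After 2 h of CCG-222740 few genes had changed, MT1X and SLC30A1 among them in both lines. MT1X, a metallothionein that binds zinc and copper, rose by 3.10 ± 0.21 in UACC62P and 2.51 ± 0.18 in UACC62R, and SLC30A1, which exports zinc from the cell, by 2.31 ± 0.19 and 1.98 ± 0.17. In UACC62P, MT2A (1.73 ± 0.12), ENTREP1 (1.56 ± 0.25) and ZBTB2 (0.86 ± 0.12) also rose, and all 3 passed in UACC62R too, where ENTREP1 went from 0.939 to 5.52 CPM. MOGS (-0.70 ± 0.11), the first glucosidase of N-glycan trimming, CHPF2 (-0.75 ± 0.11) and MINPP1 (-1.16 ± 0.14) fell. In UACC62R, MT1G (1.53 ± 0.23), the immediate early gene EGR1 (1.34 ± 0.19) and the clock gene PER1 (1.24 ± 0.20) rose. VEGFC (-0.58 ± 0.10), CHPF2 (-0.58 ± 0.09), MOGS (-0.73 ± 0.09), MINPP1 (-0.87 ± 0.11) and DNAJC3 (-1.20 ± 0.12), an ER co-chaperone, fell. The heat shock genes were called as a list in both lines (camera adjusted p = 9.74e-06 in UACC62P and 2.45e-08 in UACC62R) and so were the immediate early genes (0.00174 and 9.46e-07). In UACC62R, NRF2 targets and glycolysis and hypoxia genes were called upwards too (camera adjusted p = 0.00599 each). With an estimated correlation these calls were lost (adjusted p = 0.953 for both lists in UACC62P, 0.389 for both in UACC62R, 0.663 and 0.988 for the last 2). None of these genes passed in 16 libraries, where edgeR called 0 genes in either line and DESeq2 called 1328 and 10, with 4053 and 295 genes at an unadjusted p under 0.05. The UACC62P values include the library labelled UACC62P 2 h replicate 1, which resembled UACC62R, so they hold part of the difference between the lines. For UACC62R, 295 is fewer than a p under 0.05 would give by chance among the 19352 genes tested. In 15 libraries edgeR called 6 up and 3 down in UACC62P and 10 up and 5 down in UACC62R, and with the replicate block 20 and 10, and 48 and 26. The UACC62P count dropped to 4 and 3 without 0 h replicate 1 or 2, and the UACC62R count to 8 and 6 without 0 h replicate 1 or 2 and to 5 without 2 h replicate 1.

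At 6 h the metallothionein genes MT1X and MT1G and the heat shock gene HSPA1A were above their 0 h levels in both lines. In UACC62P, MT1X (ENSG00000187193) rose by 4.30 ± 0.20, from 14.9 ± 1.81 to 293 ± 87.3 CPM (SD), MT1G by 3.19 ± 0.26, MT2A by 3.12 ± 0.11, the inducible HSP70 gene HSPA1A by 2.86 ± 0.34 and SUSD5 by 1.63 ± 0.18. These 5 genes were also called in 16 libraries, as were the falls of SGSH (-0.75 ± 0.09), a lysosomal sulfatase gene, MOGS (-1.07 ± 0.09) and ANGPTL2 (-1.54 ± 0.11). HMOX1, which degrades haem, rose by 3.51 ± 0.55, a call made in 15 libraries and not in 16, where the fold was 3.52. Its replicates lay far apart (445 ± 448 CPM, SD). The zinc importer gene SLC39A10 (-1.79 ± 0.16), CHSY3 (-1.91 ± 0.34), LGI3 (from 9.17 to 3.25 CPM) and PCDHA7 (-1.48 ± 0.18) had falls called in 15 libraries only, as had MITF (-0.65 ± 0.10; also -0.65 in 16 libraries). In UACC62R, MT1X (3.36 ± 0.18), MT1G (2.90 ± 0.23), SGSH (-0.81 ± 0.09) and MOGS (-1.01 ± 0.09) were called in both fits. The rises of HSPA1A (2.41 ± 0.32), HSPA1B (2.31 ± 0.37) and SLC30A1 (1.94 ± 0.17) and the falls of DNAJC3 (-1.52 ± 0.12), ANGPTL2 (-1.33 ± 0.12), CHPF2 (-1.32 ± 0.09), SLC39A10 (-1.32 ± 0.15) and PCDHA7 (-1.27 ± 0.17) were called in 15 libraries only.

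Of the 12 heat shock genes, 5 rose in UACC62P and 4 in UACC62R at 6 h, and 0 fell. The examples were HSPH1 (1.00) and BAG3 (0.69) in UACC62P and BAG3 (0.66) and HSPA8 (0.62) in UACC62R (9 and 11 rose when adjusted over the list alone, 11 and 12 with the replicate block; camera adjusted p = 1.31e-07 and 2.62e-11). Of the 19 glycolysis and hypoxia genes, 2 rose in UACC62P (SLC2A1 0.85, P4HA1 0.37) and 1 in UACC62R (P4HA1 0.40), and 0 fell (camera adjusted p = 0.000524 and 0.000343). Both lists lost the call with an estimated correlation (adjusted p = 0.750 and 0.667 for heat shock, 0.750 and 0.926 for glycolysis). In UACC62P, 2 ATF4 response genes rose (SLC3A2 1.82, SLC7A11 0.81; camera adjusted p = 0.00487). So did 3 NRF2 targets (HMOX1, GCLM 0.88, SLC7A11; camera adjusted p = 0.00996). In contrast, 3 ER chaperones fell and 1 rose (DNAJC3 -1.15, PDIA4 -1.08, MANF -0.73, DNAJB9 1.27; camera adjusted p = 0.0382). MAPK output and the genes of dedifferentiated or invasive melanoma were called upwards with 0 members past the test (camera adjusted p = 0.00556 and 0.0382). These 5 calls were lost with an estimated correlation (adjusted p = 0.758 for the last and 0.750 for the others). In 16 libraries 7 genes rose and 3 fell in UACC62P, and 3 rose and 2 fell in UACC62R. In 15 libraries 172 rose and 136 fell, and 77 rose and 58 fell, and with the replicate block 739 and 676, and 352 and 214. Leaving out 1 of the 4 libraries compared left 59 to 205 calls in UACC62P (59 without 6 h replicate 2, 90 and 110 without 0 h replicates 2 and 1, 205 without 6 h replicate 1) and 56 to 71 in UACC62R (56 and 71 without 6 h replicates 1 and 2, 66 and 64 without 0 h replicates 1 and 2).

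In UACC62P at 24 h, genes of cystine import and some ER genes rose, while other ER genes, such as PDIA4 and MOGS, fell. SLC3A2 and SLC7A11, the chains of the cystine importer, rose by 1.69 ± 0.15 and 1.51 ± 0.12, and DNAJB9, an ER co-chaperone, rose by 1.69 ± 0.23. MT2A stayed high (2.38 ± 0.10), and the zinc importer gene SLC39A10 fell by -2.07 ± 0.16. The count was 20 genes up and 9 down in 16 libraries, 445 and 335 in 15 libraries, and 1224 and 1224 with the replicate block. The rises of SLC3A2 and SLC7A11 were called in 15 libraries only, and those of DNAJB9 and MT2A in both fits. Rises called in both fits included TTC17 (1.36 ± 0.09), CSGALNACT2 (1.21 ± 0.12), TMEM131 (1.09 ± 0.11), MIA3 (1.05 ± 0.09), needed for the ER export of collagen, TRAM1 (1.00 ± 0.08) and SSR1 (0.97 ± 0.07), which act at the ER translocon, SLC33A1 (0.98 ± 0.10) and ALG2 (0.95 ± 0.11), a mannosyltransferase of N-glycan assembly. MT1X (1.77 ± 0.19), ADM2 (1.68 ± 0.36), SMIM14 (1.48 ± 0.12), MGAM2 (1.47 ± 0.33) and METTL7B (1.42 ± 0.23) had rises called in 15 libraries only. Besides SLC39A10, the falls called in both fits were in ANGPTL2 (-1.80 ± 0.12), CCN3 (-1.65 ± 0.12), a matricellular gene, PDIA4 (-1.32 ± 0.12), a protein disulfide isomerase, MMP14 (-1.31 ± 0.13), a membrane metalloprotease, JAM3 (-1.01 ± 0.08), SMPD1 (-0.84 ± 0.12), MOGS (-0.79 ± 0.08) and FKBP10 (-0.60 ± 0.08). The drug transporter gene ABCB5 (-2.18 ± 0.36), LGI3 (-1.91 ± 0.24), CHSY3 (-1.54 ± 0.34), PCDHA7 (-1.53 ± 0.18), GADD45B (-1.48 ± 0.29), TRIM63 (-1.39 ± 0.32) and GALNT3 (-1.37 ± 0.21) had falls called in 15 libraries only.

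Of the 19 ATF4 and amino acid response genes, 8 rose in UACC62P at 24 h and 0 fell, with ASNS (1.15), which makes asparagine, and CHAC1 (to 32.2 ± 5.63 CPM, SD) besides the importer genes (15 rose when adjusted over the list alone; median 0.50, camera adjusted p = 1.28e-08). Of 24 G1/S and DNA replication genes 5 fell, including MCM4 (-0.42), MCM7 (-0.41) and PCNA (-0.39), and of 24 G2/M genes 3 fell, AURKB (-0.77), PLK1 (-0.72) and CDC20 (-0.60). Adjusted over the list alone 14 and 19 fell, and with the replicate block 15 and 23 (camera adjusted p = 1.28e-08 for each list). The members of these 3 lists named here did not pass the test in 16 libraries. With an estimated correlation the 3 calls were lost (adjusted p = 0.392, 0.604 and 0.808). NRF2 targets rose in 3 of 18 genes (SLC7A11, ME1 0.42, PGD 0.29; camera adjusted p = 0.000427). Melanocyte genes fell in 4 of 17 and rose in 1 (MLPH -0.52, RAB27A -0.49, MITF -0.46, MLANA -0.46; camera adjusted p = 0.0193). MAPK output rose in 2 of 15 genes and fell in 1 (EGR1 0.89, IER3 0.36, FOSL1 -0.43; camera adjusted p = 0.0193). Genes of glycolysis and hypoxia rose in 2 of 19 (P4HA1 0.68, SLC2A1 0.65; camera adjusted p = 0.0343). Cholesterol synthesis was called upwards with 0 of 23 genes past the test (MSMO1 0.58; camera adjusted p = 0.0349). These 5 calls were lost with an estimated correlation (adjusted p = 0.604, 0.392, 0.822, 0.822 and 0.822, in that order).

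The targets of the pathway were not called as lists in UACC62P. Of the MRTF/SRF targets 3 fell and 1 rose (ITGA5 -1.17, TAGLN2 -0.51, ACTB -0.35, CSRP1 0.79; 5 and 2 adjusted over the list alone; camera adjusted p = 0.531), with a median of -0.04 and a mean of 0.03, the test pointing down. Of the YAP/TAZ targets 2 fell, CCN1 (-0.97 ± 0.16) and NT5E (-0.72 ± 0.12) (camera adjusted p = 0.156). CCN2 (-0.48 ± 0.14), AXL (0.49 ± 0.19), NGFR (0.49 ± 0.38), MRTFA (-0.07 ± 0.09), MRTFB (0.10 ± 0.16), SRF (-0.04 ± 0.09), SOX10 (-0.04 ± 0.10), BRAF (0.16 ± 0.11), ACTA2 (0.00 ± 0.12) and TAGLN (0.56 ± 0.44) did not pass the test. ANKRD1 had at most 4 reads over a UACC62P group, and no fold is given. Of the other lists at 24 h, immediate early genes had 2 up and 2 down (NR4A3 -1.33), ER chaperones 3 up and 4 down (DNAJC3 -0.81), p53 targets 1 up and 2 down (TNFRSF10B 0.39, DDB2 -0.39), extracellular matrix 2 up and 2 down (LAMB1 0.98, THBS1 -0.51), invasive melanoma 1 and 1 (CD44 0.29), NF-kB targets 1 up (LIF 0.47) and the markers of other cell types 1 up (KRT18 0.50). Aryl hydrocarbon receptor targets, interferon-stimulated genes and heat shock genes had 0 called by edgeR. Leaving out a library left 377 and 259 calls without 0 h replicate 1 or 2 and 225 and 309 without 24 h replicate 1 or 2 in 15 libraries, and 4, 2, 1 and 3 in 16.

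In UACC62R at 24 h, many MRTF/SRF and YAP/TAZ targets and 23 of 24 DNA replication genes fell, and some ER, antioxidant and cystine import genes rose. CCN1 (ENSG00000142871) and CCN2 (ENSG00000118523), matricellular genes and standard readouts of YAP and MRTF, fell by -2.16 ± 0.13 (94.3 ± 1.09 to 21.1 ± 2.97 CPM, SD) and -1.69 ± 0.13 (106 ± 6.60 to 32.8 ± 3.41 CPM, SD). ITGA5, the fibronectin receptor subunit, fell by -1.83 ± 0.14, and DNAJB9 rose from 22.9 ± 0.252 to 104 ± 19.1 CPM (SD). The count was 171 genes up and 173 down in 16 libraries, 1315 and 1669 in 15 libraries, and 2230 and 2668 with the replicate block. The largest rises called in both fits included DNAJB9, SLC3A2 (1.84 ± 0.15), MT1X (1.83 ± 0.17), GDF15 (1.63 ± 0.16), a stress-induced cytokine gene, METTL7B (1.56 ± 0.22), BTN3A3 (1.54 ± 0.13), CREBRF (1.44 ± 0.16), CYP1A1 (1.44 ± 0.16), the standard target of the aryl hydrocarbon receptor, SLC33A1 (1.36 ± 0.10) and MT1G (1.36 ± 0.23). PADI4 (1.87 ± 0.48), CYP4F11 (1.77 ± 0.30), the laminin gene LAMB3 (1.72 ± 0.17), JUP (1.63 ± 0.36) and SNED1 (1.61 ± 0.35) had rises called in 15 libraries only. The largest falls called in both fits included PCDHA7 (-1.74 ± 0.18), ANGPTL2 (-1.69 ± 0.12), NTM (-1.67 ± 0.19), ADAMTS1 (-1.62 ± 0.24), SLC39A10 (-1.60 ± 0.16), CDCA7 (-1.56 ± 0.14), the checkpoint gene CLSPN (-1.42 ± 0.18), ZNF367 (-1.39 ± 0.15), HBEGF (-1.39 ± 0.11), an EGF receptor ligand, and OLFM2 (-1.36 ± 0.19). KRT80 (-2.73 ± 0.12), EFEMP1 (-2.47 ± 0.12), CCN1, SERPINB7 (-2.02 ± 0.20), LYPD1 (-1.84 ± 0.36), ITGA5, ADAMTS15 (-1.72 ± 0.26), ADAM19 (-1.71 ± 0.22) and FSTL3 (-1.70 ± 0.23) had falls called in 15 libraries only.

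Of the 22 YAP/TAZ targets, 15 fell in UACC62R at 24 h and 0 rose, with CRIM1 (-1.62) and AMOTL2 (-1.27) besides the CCN genes (16 fell when adjusted over the list alone; median -0.74, camera adjusted p = 1.21e-11). Of the 23 MRTF/SRF targets, 14 fell and 0 rose, with TPM1 (-1.19) and the actin genes ACTG1 (-1.13) and ACTB (-0.98) (16 fell and 2 rose adjusted over the list alone; median -0.43, camera adjusted p = 3.55e-08). Of the 24 G1/S and DNA replication genes 23 fell, with CCNE2 (-1.31), MCM10 (-1.29), E2F2 (-1.24) and CDT1 (-1.24) (23 adjusted over the list alone; median -0.82, camera adjusted p = 8.80e-20). Of the 24 G2/M genes 14 fell, with BIRC5 (-0.96), CCNA2 (-0.85) and KIF23 (-0.84) (22 adjusted over the list alone; median -0.61, camera adjusted p = 3.55e-08). The falls in 16 libraries numbered 1, 2, 12 and 0, in that order. Many YAP/TAZ and MRTF/SRF targets differed between the lines at 0 h, so the wider spread of the 16-library fit weighs on them. With an estimated correlation the 4 calls were lost (adjusted p = 0.164, 0.180, 0.180 and 0.451). NRF2 targets rose in 9 of 18 genes and fell in 0, with FTH1 (0.91), AKR1C3 (0.88) and NQO1 (0.67) (camera adjusted p = 4.02e-06). ER chaperones rose in 8 of 15 and fell in 2, with XBP1 (0.73), DNAJC3 (-0.85) and PDIA4 (-0.77) (camera adjusted p = 0.00224). Cholesterol synthesis genes rose in 7 of 23 and fell in 1, with CYP51A1 (0.78), SQLE (0.68) and TMEM97 (-0.75) (camera adjusted p = 0.00337). Extracellular matrix genes fell in 7 of 24 and rose in 1, with FBN1 (-0.98), THBS1 (-0.98), COL5A1 (-0.84) and LAMB1 (1.34) (camera adjusted p = 0.0299). These 4 calls were lost with an estimated correlation (adjusted p = 0.222, 0.298, 0.502 and 0.694, in that order).

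The remaining lists were not called in UACC62R at 24 h. NF-kB targets fell in 3 of 17 genes (CCL2 -1.63, CXCL1 -1.33), immediate early genes in 4 of 18 (FOSL1 -1.04, JUN -0.53), and genes of invasive melanoma in 3 of 20, with 1 up (TGFBI -1.28, CD44 0.54). ATF4 response genes had 3 up and 1 down (CEBPB 0.92, MTHFD2 -0.33), MAPK output 3 up and 1 down (SPRY4 0.84, SPRY2 0.65), melanocyte genes 3 up and 2 down (ERBB3 1.01, MLPH -0.40), p53 targets 2 up (GDF15, TNFRSF10B 0.41), interferon-stimulated genes 3 up and 1 down (OAS1 0.80, OAS3 -0.36), glycolysis and hypoxia 2 up (P4HA1 0.92, HK2 0.59) and aryl hydrocarbon receptor targets 1 up (CYP1A1). The heat shock and other cell type lists had 0 called by edgeR. SRF (-0.48 ± 0.09), AXL (-0.50 ± 0.12) and MRTFA (-0.31 ± 0.09) had falls called in 15 libraries and not in 16. MRTFB (-0.01 ± 0.15), MITF (-0.29 ± 0.11), SOX10 (0.12 ± 0.10), NGFR (1.08 ± 0.41), BRAF (0.16 ± 0.11), ACTA2 (-0.07 ± 0.11) and TAGLN (-0.20 ± 0.31) did not pass in either fit. ANKRD1 fell by -2.55 ± 0.73, from 52 to 9 reads. In 15 libraries 1251 calls were left without UACC62R 0 h replicate 2 and 1613 without 24 h replicate 1, and in 16 libraries 24 and 7 without 0 h replicate 1 or 2 and 14 and 102 without 24 h replicate 1 or 2.

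**Figure D2:**
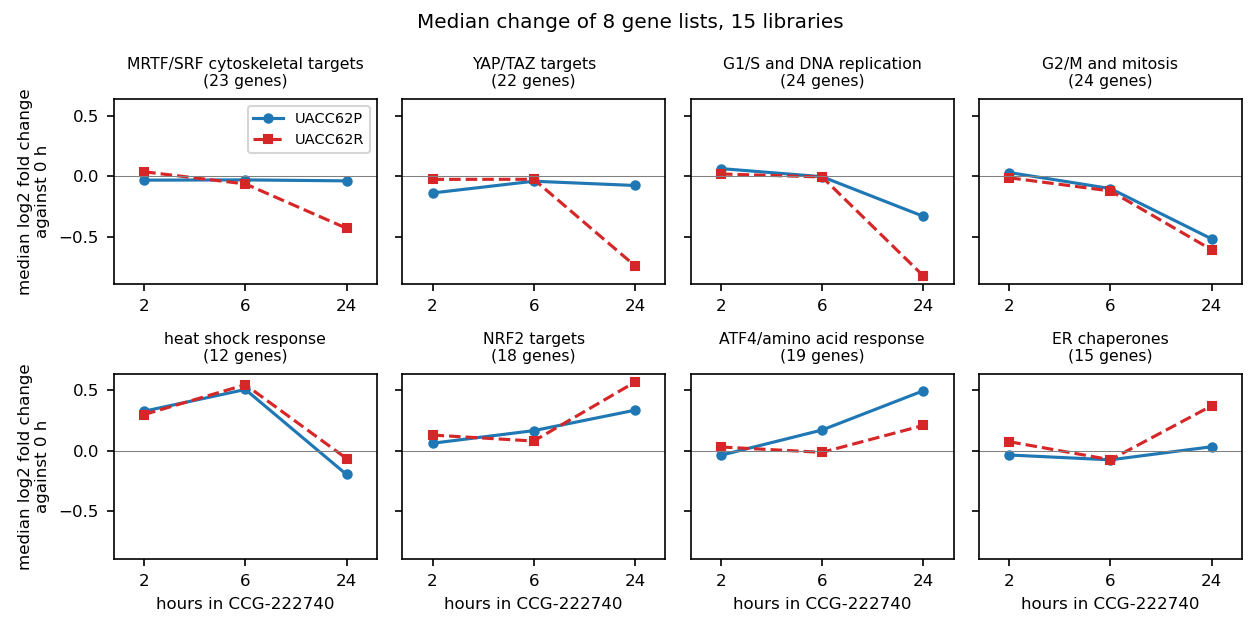
Median log2 fold change against 0 h of 8 gene lists (vertical axis) after 2, 6 and 24 h of CCG-222740 (horizontal axis, hours), in 15 libraries, with circles and solid lines for UACC62P and squares and dashed lines for UACC62R. At 24 h the YAP/TAZ median is -0.74 and the G1/S median -0.82 in UACC62R, against -0.08 and -0.33 in UACC62P.

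**Figure D3:**
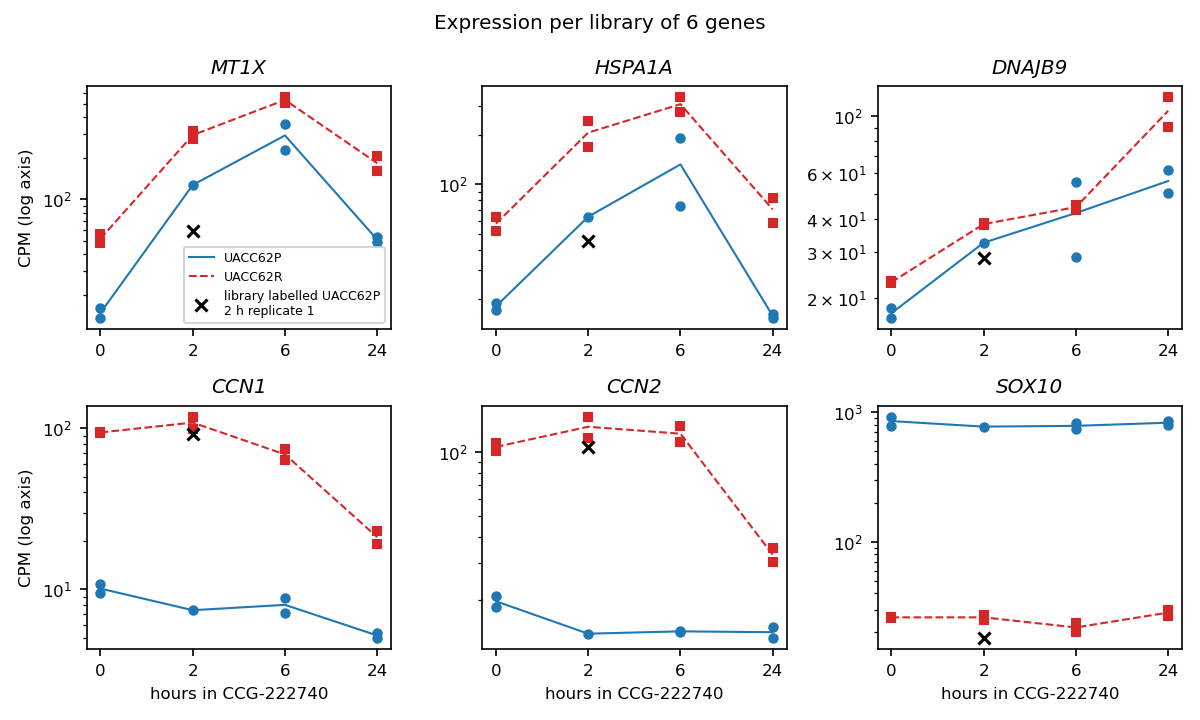
Level of 6 genes in each library (vertical axis, CPM on a log scale) at 0, 2, 6 and 24 h (horizontal axis, hours), with lines through the group means of UACC62P and UACC62R and a black cross for the library labelled UACC62P 2 h replicate 1, left out of the means. CCN1 falls to 21.1 CPM and CCN2 to 32.8 CPM in UACC62R at 24 h, and MT1X peaks at 6 h in both lines.

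The difference of response (UACC62R minus UACC62P) asked which changes from 0 h differed between the lines. Vemurafenib is not stated for the treated UACC62R libraries, and a change of it in that line alone would also appear here. At 24 h the fall of 6 of 23 MRTF/SRF and 4 of 22 YAP/TAZ targets was larger in UACC62R in 15 libraries, and that of 0 in 16 libraries. Both lists were called by camera and lost the call with an estimated correlation (adjusted p = 0.103 for each). CRIM1 differed by -1.51 ± 0.16, AMOTL2, an angiomotin that YAP induces, by -1.33 ± 0.19, CCN2 by -1.20 ± 0.18 and CCN1 by -1.19 ± 0.20. Among the cytoskeletal genes ACTG1 differed by -0.83 ± 0.15, TPM1 by -0.82 ± 0.16, PDLIM7 by -0.71 ± 0.14 and VCL, the focal adhesion protein vinculin, by -0.70 ± 0.13. By edgeR, 0 genes passed in 16 libraries (631 at an unadjusted p under 0.05, and 15 by DESeq2), 49 higher and 65 lower in 15 libraries, and 358 and 464 with the replicate block. The 631 are fewer than a p under 0.05 would give by chance among the 19352 genes tested. The other genes with the largest differences were SLC7A8 (1.46 ± 0.24), CYP1A1 (1.43 ± 0.24), RAB5IF (1.33 ± 0.24), PREX1 (1.25 ± 0.21) and the cyclooxygenase gene PTGS2 (1.21 ± 0.20) upwards, and TLN2 (-1.45 ± 0.28), MAP3K14 (-1.58 ± 0.19) and CDCA7 (-1.62 ± 0.19) downwards. AXL (-0.99 ± 0.23), SRF (-0.44 ± 0.13), TAGLN (-0.76 ± 0.53) and MRTFA (-0.23 ± 0.13) did not pass.

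Of the 22 YAP/TAZ targets 4 differed downwards at 24 h (11 adjusted over the list alone; median -0.63, camera adjusted p = 7.46e-12). Of the 23 MRTF/SRF targets 6 did so (13 adjusted over the list alone, 14 with the replicate block; median -0.48, camera adjusted p = 1.23e-10). With an estimated correlation both calls were lost (adjusted p = 0.103 for each), and under the replicate block the MRTF/SRF call held (adjusted p = 0.0464) and the YAP/TAZ call did not (adjusted p = 0.0901). Of the 24 G1/S genes 3 differed downwards, MCM6 (-0.84), MCM3 (-0.71) and MCM2 (-0.69) (17 adjusted over the list alone; camera adjusted p = 1.03e-13). Of the 15 ER chaperones 1 differed upwards, CRELD2 (0.60) (7 adjusted over the list alone; camera adjusted p = 3.40e-06). The ATF4 response differed downwards in 2 genes (SLC7A11 -0.95, MTHFD2 -0.62; camera adjusted p = 0.000532) and the extracellular matrix in 2 (FBN1 -1.32, COL6A1 -0.62; camera adjusted p = 0.00244). Melanocyte genes were called upwards (camera adjusted p = 0.0139) and genes of invasive melanoma downwards (camera adjusted p = 0.0408) with 0 members past the test by edgeR. These 6 calls were lost with an estimated correlation (adjusted p = 0.217, 0.136, 0.390, 0.516, 0.136 and 0.634, in that order). Leaving out 1 of the 8 libraries moved the 15-library count to 45 and 39 (UACC62P 0 h replicates 1 and 2), 58 and 16 (UACC62R 0 h), 11 and 22 (UACC62P 24 h) and 38 (UACC62R 24 h replicate 1).

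At 6 h MT2A alone differed in 15 libraries, by -1.63 ± 0.14, with a smaller rise in UACC62R, where it stood at 948 ± 8.59 CPM before treatment against 115 ± 13.2 CPM in UACC62P (SD, n = 2). The 16-library fit called 0 genes (225 at an unadjusted p under 0.05, fewer than by chance, and 3 by DESeq2), and the replicate block in 15 libraries gave 23 higher and 20 lower. Without UACC62P 0 h replicate 1 the count was 3, and without UACC62P 6 h replicate 1 or 2 it was 2. At 2 h edgeR called 0 genes in 16 libraries (1904 at an unadjusted p under 0.05, and 41 by DESeq2). There the UACC62P 2 h group holds the library labelled UACC62P 2 h replicate 1, so these values hold part of the difference between the lines. In 15 libraries that group had only 1 library.

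The comparison of 24 h with 2 h left out the untreated libraries. In UACC62P, CHAC1, a glutathione-degrading enzyme gene of the ATF4 response, rose between these times by 1.94 ± 0.39, SMIM14 by 1.61 ± 0.15, SLC22A31 from 3.20 to 9.04 CPM, METTL7B by 1.45 ± 0.29 and LAMB3 by 1.40 ± 0.24. In turn HSPA1B (-2.08 ± 0.45), ABCB5 (-2.06 ± 0.41), HSPA1A (from 63.3 to 15.8 CPM), RPS26 (-1.68 ± 0.22) and SLC39A10 (-1.64 ± 0.19) fell. Of these 10 only SLC39A10 was called in 16 libraries, whose own largest changes were in ALDH1L2 (1.16 ± 0.21), ALG5 (0.98 ± 0.16), CSGALNACT2 (0.91 ± 0.15), TSPYL2 (0.90 ± 0.16), LAMB1 (0.84 ± 0.11), RGS2 (-1.44 ± 0.21), CCN3 (-1.39 ± 0.14), FOSL1 (-0.79 ± 0.10) and SMPD1 (-0.76 ± 0.14), given here as fitted in 15 libraries. In UACC62R, PDK4 (1.91 ± 0.21), DNAJB9 (1.45 ± 0.22), METTL7B (1.42 ± 0.22), CYP1A1 (1.41 ± 0.16) and CREBRF (1.34 ± 0.16) rose in both fits. NTM (-1.62 ± 0.19), CLSPN (-1.42 ± 0.18), CCNE2 (-1.39 ± 0.15), SIK1 (-1.37 ± 0.14) and OLFM2 (-1.36 ± 0.19) fell in both fits. PTGS2 (1.89 ± 0.11), PADI4 (1.79 ± 0.48), SNED1 (1.63 ± 0.35), LAMB3 (1.63 ± 0.17), KRT80 (-2.47 ± 0.12), CCN1 (-2.36 ± 0.13), EFEMP1 (-2.13 ± 0.12), CCN2 (from 132 to 32.8 CPM) and SERPINB7 (-1.91 ± 0.20) had changes called in 15 libraries only. The counts were 20 up and 6 down in UACC62P and 106 and 106 in UACC62R in 16 libraries. They were 102 and 68, and 1238 and 1721 in 15 libraries, and 397 and 326, and 2195 and 2771 with the replicate block. The share of rises among the UACC62R calls was 41.8% in 15 libraries, against 52.8% when scaled by library size alone. Without UACC62P 24 h replicate 1 or 2 the 15-library count was 31 or 77, and it was 1233 without UACC62R 2 h replicate 2 and 1529 without UACC62R 24 h replicate 1.

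The responses of the lines at 24 h shared many genes. In 15 libraries 318 genes rose in both lines (28.9 would overlap by chance from n1 x n2 / N), 185 fell in both (27.6 by chance) and 6 went opposite ways. Of the 780 genes called in UACC62P, 704 had the same sign in UACC62R. In 16 libraries 17 rose in both (0.177 by chance) and 7 fell in both (0.0805 by chance). The comparisons shared no library. A separate batch of the 0 h libraries of both lines could still add shared changes. Only the comparison of 24 h with 2 h leaves those libraries out. Across all genes, which are not independent replicates, the log2 fold changes of the lines correlated at Pearson r = 0.178 and a Spearman coefficient of 0.344 in 16 libraries and at 0.155 and 0.321 in 15. Among genes with at least 5 CPM they correlated at r = 0.490 and 0.493, and among genes called in either line at 0.824 (349 genes, 16 libraries) and 0.504 (3255 genes, 15 libraries). The called genes were chosen by the same fold changes, and differently in each fit. Their values therefore do not compare with those of all genes or with each other. At 6 h, 51 genes rose in both lines (0.653 by chance) and 34 fell in both (0.389 by chance) in 15 libraries, and 0 went opposite ways. Between 2 h and 24 h, 83 rose in both (6.23 by chance) and 42 fell in both (5.77 by chance), with r = 0.128 in 15 libraries and 0.0984 in 16.

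A last comparison asked whether the compound moved the genes that set UACC62R apart from UACC62P. The set was taken at 2 h, so that it shared no library with the comparisons of 24 h and 0 h. In 16 libraries it held only 6 genes higher and 8 lower in UACC62R, and was called in neither line (camera adjusted p = 0.875 for both sets in UACC62R, 0.231 and 0.340 in UACC62P). In 15 libraries it held 2973 higher and 1836 lower genes. Of the higher ones, 225 rose and 246 fell in UACC62R at 24 h (median 0.08, camera adjusted p = 0.481), and of the lower ones 142 rose and 179 fell (median 0, camera adjusted p = 0.928, the test pointing down). In UACC62P, 89 of the higher genes rose and 31 fell (median 0.12, camera adjusted p = 0.00248), and 28 of the lower genes rose and 87 fell (median -0.07, camera adjusted p = 0.0111). Both UACC62P calls were lost with an estimated correlation (adjusted p = 0.201 for each). The set taken at 0 h was also followed from 2 h to 24 h, with 1 library of UACC62P at 2 h. There the UACC62P median was 0.174 for the higher genes and -0.00335 for the lower ones, against 0.0164 for all genes. The fall of the lower genes thus depended on the choice of set.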

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

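These effects differed between the lines in 15 libraries. None of the genes named here passed the difference test in 16 libraries. At 6 h MT2A rose less in UACC62R (-1.633, log2 difference). At 24 h the difference, UACC62R minus UACC62P, was positive for SLC7A8 (1.456), CYP1A1 (1.431), RAB5IF (1.331), PREX1 (1.248) and PTGS2 (1.211). It was negative for AMOTL2 (-1.333), TLN2 (-1.452), CRIM1 (-1.509), MAP3K14 (-1.584) and CDCA7 (-1.624). The median differences of the lists called at 24 h were -0.4809 for MRTF/SRF targets, -0.6275 for YAP/TAZ targets, 0.1695 for melanocyte differentiation, -0.2132 for dedifferentiated or invasive melanoma, -0.4833 for G1/S and DNA replication, -0.408 for the ATF4 response, 0.3086 for ER chaperones and -0.2652 for the extracellular matrix. All 8 list calls by camera were lost with an estimated correlation (adjusted p = 0.103 to 0.634). When the replicate block was added, the MRTF/SRF call held (adjusted p = 0.0464) and the YAP/TAZ call did not.

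Among shares of reads not assigned to a gene, 4.66% lay in no gene in the library labelled UACC62P 2 h replicate 1 and 4.24% in UACC62R 24 h replicate 2, above the 0 h libraries (3.43 to 4.23%). In the library labelled UACC62P 2 h replicate 1, 6.12% of reads were not aligned (9.33 to 17.8% in the other 15) and 1.32% of reads in genes were mitochondrial (1.54 to 3.29% in the other 15). In UACC62P 6 h replicate 1, 6.81% lay in more than 1 gene (0 h libraries 6.16 to 6.78%). Reads aligned to more than 1 place made up 21.3 and 22.0% in UACC62P 6 h replicates 1 and 2 (at most 21% in the 0 h libraries). Reads not aligned made up 13.5 to 17.8% at 0 h. At 6 h they made up 10.2 and 9.93% in UACC62P and 9.76 and 9.33% in UACC62R. At 24 h they made up 13.7 and 11.9% in UACC62P and 12.7 and 10.8% in UACC62R. Whether this bears on the gene changes was not tested.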

How the results depend on the processing

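Counts of genes called are given here as 16-library totals for other settings, then for 15 libraries without the library labelled UACC62P 2 h replicate 1. For UACC62P at 2 h, where the 16 libraries called 0 genes, scaling by library size alone called 2, a filter of 1 count 3305, a filter of 5 CPM 3 and DESeq2 1328. The 15 libraries called 9, 14 with DESeq2 and 30 with the replicate block. Leaving out 1 library gave 0 to 10367 in 16 libraries, the highest without UACC62P 2 h replicate 2, and 3 to 4 in 15. For UACC62R at 2 h, where the 16 libraries called 0, the filter of 1 count called 23, DESeq2 10 and the libraries compared alone 15. The 15 libraries called 15, 43 with DESeq2, 74 with the block, and 5 to 16 with 1 library left out.

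For UACC62P at 6 h (10 in 16 libraries), the filter of 1 count called 119, DESeq2 106, the libraries compared alone 281 and the replicate block 17, and leaving out 1 library gave 0 to 8. The fit of 15 libraries called 308, 653 with DESeq2, 1415 with the block, and 59 to 205 with 1 left out. For UACC62R at 6 h (5 in 16 libraries), the filter of 1 count called 70, DESeq2 66 and the libraries compared alone 55, and leaving out 1 library gave 0 to 3. The fit of 15 libraries called 135, 293 with DESeq2, 566 with the block, and 56 to 71 with 1 left out.

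For UACC62P at 24 h (29 in 16 libraries), the filter of 1 count called 201, that of 5 CPM 62, DESeq2 233, a minimum absolute log2 fold change of 1 left 13, the libraries compared alone called 1228 and the block 75, and leaving out 1 library gave 1 to 4. Fitting 15 libraries called 780, 1289 with DESeq2, 2448 with the block, and 225 to 377 with 1 left out. For UACC62R at 24 h (344 in 16 libraries), the filter of 1 count called 860, that of 5 CPM 531, DESeq2 1046, the minimum change left 77, the libraries compared alone called 1600 and the block 668, and leaving out 1 library gave 7 to 102. Fitting 15 libraries called 2984, 4898 with the block, and 1251 to 2811 with 1 left out. For the lines at 0 h (7847 in 16 libraries), the minimum change left 4602, the 15 libraries with the block called 11896, and leaving out 1 library gave 0 to 2834 in 16 libraries.

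For the difference of response, where the 16 libraries called 0 at each time, the filter of 1 count called 1714 at 2 h, 7 at 6 h and 34 at 24 h, and DESeq2 41, 3 and 15. The libraries compared alone called 1 at 6 h and 38 at 24 h. The 15 libraries called 1 at 6 h and 114 at 24 h, with DESeq2 1, 23 and 399 at 2, 6 and 24 h, with the block 43 at 6 h and 822 at 24 h, and with 5 CPM 174 at 24 h. Leaving out 1 library gave 0 to 8378 at 2 h in 16 libraries, the highest without UACC62P 2 h replicate 2. In 15 libraries it gave 1 to 3 at 6 h and 11 to 137 at 24 h.

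For 24 h against 2 h in UACC62P (26 in 16 libraries), the filter of 1 count called 3081, that of 5 CPM 50, DESeq2 1684, the minimum change left 8, the libraries compared alone called 0 and the block 65, and leaving out 1 library gave 0 to 9906, the highest without UACC62P 2 h replicate 2. The fit of 15 libraries called 170, 434 with DESeq2, 723 with the block, and 31 to 77 with 1 left out. In UACC62R (212), the filter of 1 count called 775, that of 5 CPM 435, DESeq2 974, the minimum change left 46, the libraries compared alone called 1605 and the block 601, and leaving out 1 library gave 1 to 16. The fit of 15 libraries called 2959, 4966 with the block, and 1233 to 2593 with 1 left out.

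The list tests called 63 results in 16 libraries, 0 with an estimated correlation and 23 with fry. In 15 libraries an estimated correlation left 1 call without the block and another 1 with it. The first was melanocyte differentiation between the lines at 0 h, lost with the block. The other was MRTF/SRF targets in the difference of response at 24 h, lost without the block. The correlation between the lines (0.178) was 0.0984 at 24 h against 2 h, 0.490 at 5 CPM, 0.824 among called genes, and 0.155, 0.493 and 0.504 in 15 libraries. In UACC62P the median of the genes higher in UACC62R changed sign to -1.47 for the 0 h set at 24 h against 2 h in 16 libraries, where the 2 h group holds the library labelled UACC62P 2 h replicate 1, and was 0.174 without that library. For the 2 h set it was 0.123 in 15 libraries. For the lower genes the 2 h set had 0.199 in 16 libraries and changed sign to -0.0663 in 15, and the 0 h set at 24 h against 2 h had 0.599 and -0.00335. In 16 libraries 3 genes that were called in 15 changed sign, CHPF2 (0.0147) in UACC62P at 2 h, and SMIM14 (-0.563, and -0.423 with the block) and LAMB3 (-0.0723) in UACC62P at 24 h against 2 h. The fits of 16 and 15 libraries differ only by the library labelled UACC62P 2 h replicate 1, which held 238 CPM of CHPF2, 49.9 CPM of SMIM14 and 90.6 CPM of LAMB3, against 99.4, 6.20 and 19.9 CPM in the other UACC62P 2 h library. Without UACC62P 2 h replicate 2, the library labelled UACC62P 2 h replicate 1 was alone in its group. Those counts therefore hold the difference between the lines. Every other 16-library comparison with UACC62P 2 h that keeps this library also holds part of that difference. For the other changes listed here the cause was not tested.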

Other observations

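Genes that carry secretory proteins into the ER and attach N-glycans to them had not been looked at as a group. The list was written after SSR1, TRAM1 and ALG2 had been seen to rise, and holds 25 other genes, so the test was chosen only after that result. At 24 h, 16 of the 25 rose in UACC62P and 21 in UACC62R and 0 fell, with medians of 0.42 and 0.53 (camera adjusted p = 1.51e-16 and 8.98e-17). With an estimated correlation both camera calls stayed under 0.05 (adjusted p = 0.0150 for each, unadjusted 0.00351 in UACC62P and 0.00321 in UACC62R). This list was adjusted over its own 12 comparisons, and the 21 lists over the lists within a comparison. The adjusted values therefore do not compare with those of the calls lost above. SEC61A1, the channel of the translocon, rose by 0.60 ± 0.07 in UACC62P and 0.84 ± 0.07 in UACC62R, SSR3 by 0.85 and 0.86, STT3A, a catalytic subunit of the oligosaccharyltransferase, by 0.78 and 0.82, and RPN1 by 0.67 and 0.80. The signal peptidase genes SEC11A and SPCS3 did not pass. In 16 libraries 2 and 12 of the 25 passed. At 6 h edgeR called 0 of them in either line, while camera called the list upwards in both (adjusted p = 0.00014 in UACC62P and 1.03e-05 in UACC62R), calls lost with an estimated correlation (adjusted p = 0.165 and 0.124). At 24 h 0 differed between the lines (median difference 0.13, camera adjusted p = 0.00207, and adjusted p = 0.246 with an estimated correlation).

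The 3 tests on the library labelled UACC62P 2 h replicate 1 were chosen only after the result was seen. RNA of both lines mixed in 1 library would leave UACC62P transcripts in it, and their median share was 0.052%. An effect of CCG-222740 at 2 h on UACC62P would move the other UACC62P 2 h library too, which lay at -0.028 on the scale between the lines. A wrong label or wrong file for a UACC62R culture remains open, because the position of 0.984 is the observation that raised the question. Over the 15 genes called at 2 h in UACC62R, the library lay nearer to untreated UACC62R than to 2 h for 14. That bears on treatment, and how the library came by its label cannot be read from the counts.

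Of the MRTF/SRF and YAP/TAZ targets, 6 of 23 and 4 of 22 fell more in UACC62R than in UACC62P at 24 h in 15 libraries and 0 in 16, and both list calls were lost with an estimated correlation (adjusted p = 0.103 for each). With the replicate block the MRTF/SRF call held under that setting (adjusted p = 0.0464) and the YAP/TAZ call did not. In tests fixed before they were run but after that result was seen, scaling between libraries could only shift all genes alike, but with library size alone the median difference was -0.5249 for both lists together and -0.0114 for all genes. A low starting level in UACC62P could leave too few reads to show a fall, but members with at least 10 CPM there had a median of -0.4978 (31 of 32 negative). That cut bears only on a shortage of reads. It cannot decide whether targets that started higher in UACC62R had more expression to lose. Time in culture in place of the drug remains open, because 0 of the libraries used were kept 24 h without CCG-222740. A change of vemurafenib in UACC62R alone also remains open, because vemurafenib is not stated for its treated libraries.

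The 0 h libraries carry other label texts than the treated ones, and this test was chosen only after the result was seen. A separate library or sequencing batch for the 0 h libraries could change many genes already at 2 h. In UACC62R 15 genes passed by edgeR (15 libraries), 43 by DESeq2 and 74 with the replicate block. A test of 2 against 2 libraries can miss small shifts, so a separate batch remains open. A response of the metallothionein family as a whole could not be examined, since 0 members not yet looked at had enough counts to test. Same-numbered libraries shared deviations across groups, and taking them as pairs in a block raised the count for UACC62R at 24 h to 4898 in 15 libraries. That pairing suggests the replicate numbers stand for batches, though a label for this is not given in the sources used here.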
